A study of Mus musculus with 9 samples.

How the data were processed

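Gene expression was measured with Affymetrix arrays in conventional dendritic cells (CDC), natural killer cells (NK) and interferon-producing killer dendritic cells (IKDC) freshly sorted from naive BALB/c mice aged 6 to 8 weeks. Per the labels, RNA was taken up in TRIzol and cleaned on RNeasy columns, and biotin-labelled cRNA was made from 6 µg of total RNA. The deposited values are linear signal intensity per probe set, and the authors had scaled each array. The mean intensity between the 2nd and 98th percentiles lay between 149.9477 and 149.9596 on the 9 arrays, and the software behind it is not given in the sources used here. The table held 45101 probe sets with 0 missing values.

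The 75th percentile of the log2 intensities differed by 0.208 between the highest and the lowest array, so the values were quantile normalized after an offset of 6.49 intensity units, the 20th percentile of all values, and a log2 transformation. The 64 control probe sets were left out. Of the others, 34945 carried 1 gene symbol, and the 932 with several symbols and the 9160 with none were not used for the gene tests. Each of 18161 genes was represented by its probe set with the highest mean over the 9 arrays. The 10897 genes at or above the 40th percentile of the mean, a log2 level of 5.31, were tested.

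The tests used limma 3.58.1 in R 4.3.3, with lmFit and eBayes with a trend. The 9 arrays formed 6 groups, 1 for each organ and cell type. The spread had 3 residual degrees of freedom, all from the 3 pairs of spleen arrays, and 3.43 prior degrees of freedom. Each lymph node group was a lone array, which was assumed to vary like the spleen arrays. The two-sided p-values were adjusted by the method of Benjamini and Hochberg within each comparison, with a threshold of 0.05. They measure only the spread between these samples, and the labels do not say which animals the arrays came from. All 3 residual degrees of freedom are differences between spleen arrays 1 and 2, which Xist and the Y-linked Eif2s3y place in different mice. The spread therefore includes the difference between those mice, sex included. The number of arrays limits the precision. In data simulated at these sample sizes, 75.5% of genes given a 4-fold difference between spleen IKDC and spleen NK were called and 0% of those given a 2-fold difference. At 4-fold, 17 unchanged genes were called beside 151 changed ones. Between lymph node and spleen IKDC, 22.5% of simulated 4-fold differences were called and 0% of 2-fold ones. A count of 0 between organs is therefore not evidence that they are alike. The simulation drew independent noise with 1 spread per gene for all groups. In the data, arrays of the same number deviated alike, and the replicate SD was 0.662 in IKDC, 0.42 in CDC and 0.454 in NK. The simulated shares are thus only a guide. By chance, 545 of the 10897 genes would have an unadjusted p under 0.05 in each comparison.

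The comparisons, the lists and the rule for named genes were set before the data were examined. The rule took the 8 largest folds in each direction among called genes whose arrays did not overlap, up to 4 called members of each list named in it or called, and 24 fixed genes, of which 21 were tested. For the lymph node it took the 6 largest folds in each direction. Of 25 gene lists written from general knowledge, 24 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists, then again with an estimated correlation and with fry. Camera compares the members of a list with all other genes, and fry asks whether the members move, on balance, one way. With the preset correlation, camera takes its degrees of freedom from the number of genes. Those p-values therefore do not measure how a list varies between arrays. With an estimated correlation it has only the 3 residual degrees of freedom, which leaves little power to call any list.

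The main tests did not pair arrays by replicate number, as nothing in the labels says that a number marks a shared sort or day. Arrays of the same number nevertheless deviated alike from their group means. Across genes, r was 0.412 for CDC and NK, 0.529 for CDC and IKDC and 0.486 for NK and IKDC. Genes are not independent replicates. Fits with the number as a block are given beside the results they change. The other alternatives were values as deposited, a shift to the same 75th percentile, other offsets, filters and probe set summaries, each probe set alone, other spread settings, additive models, a 2-fold minimum, spleen arrays alone and leaving out each spleen array in turn. Blocks by Xist level and by control spike ratio were added after the data were seen. Both split the spleen arrays by replicate number. The Xist block counts the lymph node arrays with spleen arrays 2, and the spike block counts them with spleen arrays 1. Organ counts with these blocks thus set the lymph node against the level of spleen arrays 2 and of spleen arrays 1. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were also used.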

Results

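The 9 arrays covered 3 cell types from 2 organs, with 2 arrays per cell type from spleen and 1 per cell type from lymph node. CDC are antigen-presenting dendritic cells, NK are cytotoxic lymphocytes, and IKDC were named for sharing features of both. The median intensity ranged from 23.4 to 41.3 and the 75th percentile from 135 to 156 intensity units. Levels below are log2 normalized intensities, and differences are on the log2 scale with their standard error from limma. Where the lower group of a called gene had a mean below the filter level of 5.31, near background, its fold was taken against that level and is given as at least that much.

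Arrays of IKDC lay near arrays of NK. Correlations across genes between IKDC and NK arrays ranged from 0.859 to 0.936, with a median of 0.916, against a median of 0.769 between CDC and IKDC and 0.738 between CDC and NK. The spleen replicates correlated at 0.948 for CDC, 0.939 for NK and 0.865 for IKDC. The IKDC replicates differed by more than 2-fold in 2135 of the 10897 genes, compared with 896 for CDC and 898 for NK. Genes are not independent replicates, so these values describe the arrays and carry no test. Spleen IKDC array 2 had the lowest median intensity of all arrays, at 23.4. Its BioB control spike, at 110.8, was also the lowest, where the other spleen arrays read 254.6 to 303.3. The ratio of signal between the ends of the actin transcript was highest on spleen IKDC array 1, at 3.23, and was 1.24 on array 2. The wider spread of the IKDC replicates may thus reflect these arrays rather than the cell type, which was not tested.

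**Figure D1:**
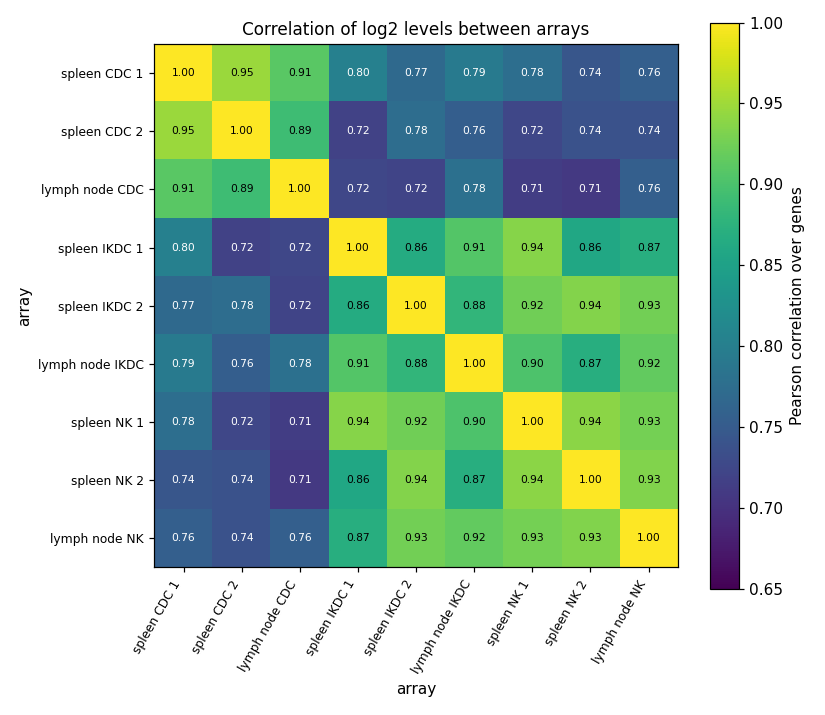
Pearson correlation across genes of the log2 levels for each pair of the 9 arrays (both axes list the arrays). IKDC and NK arrays correlate at 0.859 to 0.936, and CDC arrays correlate with IKDC arrays at 0.719 to 0.803.

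The spleen arrays also divided by replicate number. Xist, the transcript of the inactive X chromosome, was at 6.02 to 6.36 on spleen arrays 1 and at 11.43 to 12.49 on spleen arrays 2 and the lymph node arrays. Eif2s3y, a Y-linked gene, was at 8.84 to 9.40 on spleen arrays 1 and at 4.28 or below on all others. In both genes the lymph node arrays were like spleen arrays 2, so each organ test set them against a spleen array of either kind. Mki67, a marker of dividing cells, was at 10.97 and 9.35 on the CDC arrays 1 and 2, at 11.06 and 8.71 on the NK arrays and at 11.91 and 9.06 on the IKDC arrays. The 3' to 5' ratio of the BioC control spike was 0.771 to 0.810 on spleen arrays 1, 0.830 to 0.852 on the lymph node arrays and 1.13 to 1.22 on spleen arrays 2.

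Spleen IKDC were compared with spleen CDC to find what sets IKDC apart from conventional dendritic cells. Genes of cytotoxic lymphocytes were far higher in IKDC. Ncr1, which encodes the activating receptor NKp46, was at 11.26 ± 0.41 in IKDC and 5.50 ± 0.62 in CDC (SD, n = 2 each), a 54.2-fold difference (5.76 ± 0.40 SE, adjusted p = 0.00129). Ifng, the gene for interferon gamma, was at least 58.5-fold higher, Gzmb, a granzyme of cytotoxic granules, 51.9-fold, and Prf1, which encodes perforin, 36.0-fold. Flt3, a growth factor receptor of dendritic cells, was 35.1-fold lower (-5.13 ± 0.30, adjusted p = 0.00129), and Cd86, a costimulatory ligand for T cells, 16.5-fold lower. Itgax, which encodes CD11c, was at 11.13 ± 0.15 in IKDC and 12.13 ± 0.34 in CDC (adjusted p = 0.681), and H2-Aa, a class II chain, at 11.46 ± 0.78 and 12.70 ± 0.20 (adjusted p = 0.627). The H2-Aa value is uncertain, as probe sets of its multigene family can cross-hybridise.

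The test called 1129 genes between spleen IKDC and CDC, 517 higher and 612 lower in IKDC. Among the higher genes were Gimap6 (at least 39.9-fold), Crtam (at least 45.6-fold), S1pr5, a receptor for lymphocyte egress (at least 26.7-fold), and Jakmip1 (at least 57.3-fold). Among the lower genes were Rab30 (at least 18.1-fold), Sirpb1a (at least 38.9-fold) and Havcr2, the gene for TIM-3 (47.8-fold). Il1b, the gene for interleukin 1 beta, was 32.7-fold lower. With the replicate number as a block 1881 genes were called, among them all 1129. Without spleen CDC array 1 the count was 465, and without spleen CDC array 2 it was 359.

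NK receptor genes were higher in spleen IKDC than in CDC in 21 of 27 tested members, and 26 were higher when adjusted over the list alone (median 4.45, camera adjusted p = 4.2e-22). Klre1 was 48.4-fold higher and Klrk1, which encodes NKG2D, 5.52-fold. The call was lost at adjusted p = 0.122 with an estimated correlation. Cytotoxic effector genes were higher in 14 of 21 members, 18 adjusted over the list alone (median 3.11, adjusted p = 6.83e-14, and adjusted p = 0.122 with an estimated correlation). Ctsw, a cathepsin of cytotoxic cells, was 33.3-fold higher. Conventional DC genes were lower in 24 of 33 members, 29 adjusted over the list alone (median -3.48, adjusted p = 6.3e-25, and adjusted p = 0.12 with an estimated correlation). Zbtb46, a transcription factor of conventional dendritic cells, was 7.39-fold lower.

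Class II presentation genes were lower in spleen IKDC than in CDC in 11 of 18 members, 13 adjusted over the list alone (median -3.34, adjusted p = 4.28e-10, and adjusted p = 0.19 with an estimated correlation). Ciita, the master regulator of class II genes, was 20.4-fold lower, and Cd74, the invariant chain, was at 9.64 ± 1.20 in IKDC and 12.96 ± 0.19 in CDC (adjusted p = 0.064, and 0.0102 with the block). Toll-like receptor genes were lower in 10 of 17 members, 12 adjusted over the list alone (median -2.06, adjusted p = 1.24e-09, and adjusted p = 0.12 with an estimated correlation). Tlr3, a sensor of double-stranded RNA, was 28.7-fold lower. T cell genes were higher in 9 of 15 members and lower in 2 (median 2.90, adjusted p = 0.00038, and adjusted p = 0.148 with an estimated correlation), with 10 higher and 3 lower adjusted over the list alone. Cd28 was at least 29.2-fold higher and Cd4 at least 16.5-fold lower. Early NK stage genes (median 2.83, adjusted p = 1.11e-05, and adjusted p = 0.12 with an estimated correlation) and terminal NK maturation genes (median 2.20, adjusted p = 1.76e-05, and adjusted p = 0.402 with an estimated correlation) were higher. Costimulation genes (median -1.31, adjusted p = 0.000748, and adjusted p = 0.259 with an estimated correlation) and migratory DC genes (median -0.928, adjusted p = 0.0114, and adjusted p = 0.402 with an estimated correlation) were lower. Between arrays 1 and between arrays 2, the medians were 2.02 and 3.78 for T cell, -0.971 and -1.74 for costimulation and -0.517 and -0.862 for migratory DC genes. Adjusted over the list alone, the last 4 lists had 11, 9, 1 and 4 members higher and 2, 0, 7 and 10 lower. Itga2, which encodes the NK marker CD49b, differed by 1.46 ± 0.35 (adjusted p = 0.0505, and 0.03 with the block). The block also added proliferation genes (median 0.338, adjusted p = 0.00742, and adjusted p = 0.898 with an estimated correlation and no block). Their median was 0.654 between arrays 1, 0.0667 between arrays 2 and -1.18 between the lymph node arrays. In all, 10 lists were called between IKDC and CDC, and 16 without spleen IKDC array 2.

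Spleen NK were compared with spleen CDC as the reference for a cytotoxic lymphocyte. Genes of cytotoxic lymphocytes were again far higher. Ncr1 was 84.3-fold higher in NK, at 11.90 ± 0.39 against 5.50 ± 0.62 (SD, n = 2 each, adjusted p = 0.000581), Gzmb 110-fold, Ifng at least 101-fold and S1pr5 at least 54.6-fold. H2-DMb2, a class II chaperone, was at least 101-fold lower in NK, Abca3, a lipid transporter, at least 25.8-fold, and Flt3 50.6-fold. The H2-DMb2 value is uncertain, as probe sets of its multigene family can cross-hybridise. Itgam, which encodes CD11b and marks mature NK, was at 8.44 ± 1.06 in NK and 6.65 ± 0.61 in CDC (adjusted p = 0.224, and 0.0129 with the block), and H2-Aa was at 8.76 ± 3.02 and 12.70 ± 0.20 (adjusted p = 0.0967, and 0.0256 with the block).

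The test called 1473 genes between spleen NK and CDC, 713 higher and 760 lower in NK, and 2310 with the block, among them all 1473. The count was 727 without spleen CDC array 1, 510 without CDC array 2, 676 without NK array 1 and 668 without NK array 2. NK receptor genes were higher in NK in 23 of 27 members, 24 adjusted over the list alone (median 4.64, adjusted p = 4.79e-21, and adjusted p = 0.149 with an estimated correlation). Cytotoxic effector genes were higher in 16 of 21, 17 adjusted over the list alone. Their median was 3.31 (camera adjusted p = 1.16e-12, and adjusted p = 0.149 with an estimated correlation). Conventional DC genes were lower in 27 of 33, 28 adjusted over the list alone (median -3.99, adjusted p = 4.6e-25, and adjusted p = 0.149 with an estimated correlation). Terminal NK maturation genes were higher in 10 of 15, 11 adjusted over the list alone (median 3.60, adjusted p = 3.45e-09, and adjusted p = 0.251 with an estimated correlation), with Klrg1, an inhibitory receptor of mature NK, 43.9-fold higher. B cell genes were lower (median -0.994, adjusted p = 0.0296, and adjusted p = 0.315 with an estimated correlation), with 3 members higher and 7 lower adjusted over the list alone, and macrophage genes too (median -1.33, adjusted p = 0.0187, and adjusted p = 0.705 with an estimated correlation), also with 3 higher and 7 lower adjusted over the list alone. Erythroid and platelet genes were higher (median 2.28, adjusted p = 0.00928, and adjusted p = 0.251 with an estimated correlation), with 3 of 6 members higher adjusted over the list alone. Between arrays 1 and between arrays 2, the medians were -0.344 and -1.3 for B cell, -1.5 and -0.718 for macrophage and 1.53 and 2.41 for erythroid and platelet genes. In all, 14 lists were called, and the block added proliferation (median -0.395, adjusted p = 0.0127), class I presentation (median -0.241, adjusted p = 0.0421) and lymphocyte homing (median 0.678, adjusted p = 0.043). These had adjusted p = 0.929, 0.251 and 0.705 with an estimated correlation and no block.

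Spleen IKDC were compared with spleen NK to ask whether their transcripts differ. Ncr1 was at 11.26 ± 0.41 in IKDC and 11.90 ± 0.39 in NK (SD, n = 2 each), Prf1 at 11.27 ± 0.46 and 11.82 ± 0.51, and Ifng at 11.18 ± 0.01 and 11.97 ± 0.25. Gzma, another granzyme, was at 13.17 ± 0.03 and 13.29 ± 0.17. Itgam was at 6.56 ± 1.48 and 8.44 ± 1.06, a difference of -1.88 ± 0.80 (adjusted p = 0.857), and was -2.33 in the lymph node pair. Itgax was at 11.13 ± 0.15 in IKDC and 9.30 ± 2.86 in NK, where array 1 read 11.32 and array 2 read 7.27. H2-Aa likewise read 10.89 and 6.62 on the NK arrays and 12.01 and 10.90 on the IKDC arrays.

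Limma called 0 of 10897 genes between spleen IKDC and NK, and 597 had an unadjusted p under 0.05 where 545 would by chance. The smallest adjusted p was 0.846, or 0.342 with the block, which also called 0 genes. The count of genes apart from both NK and CDC could therefore only be 0. This is not evidence that the cell types are alike, since 0% of simulated 2-fold differences were called at this size.

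**Figure D2:**
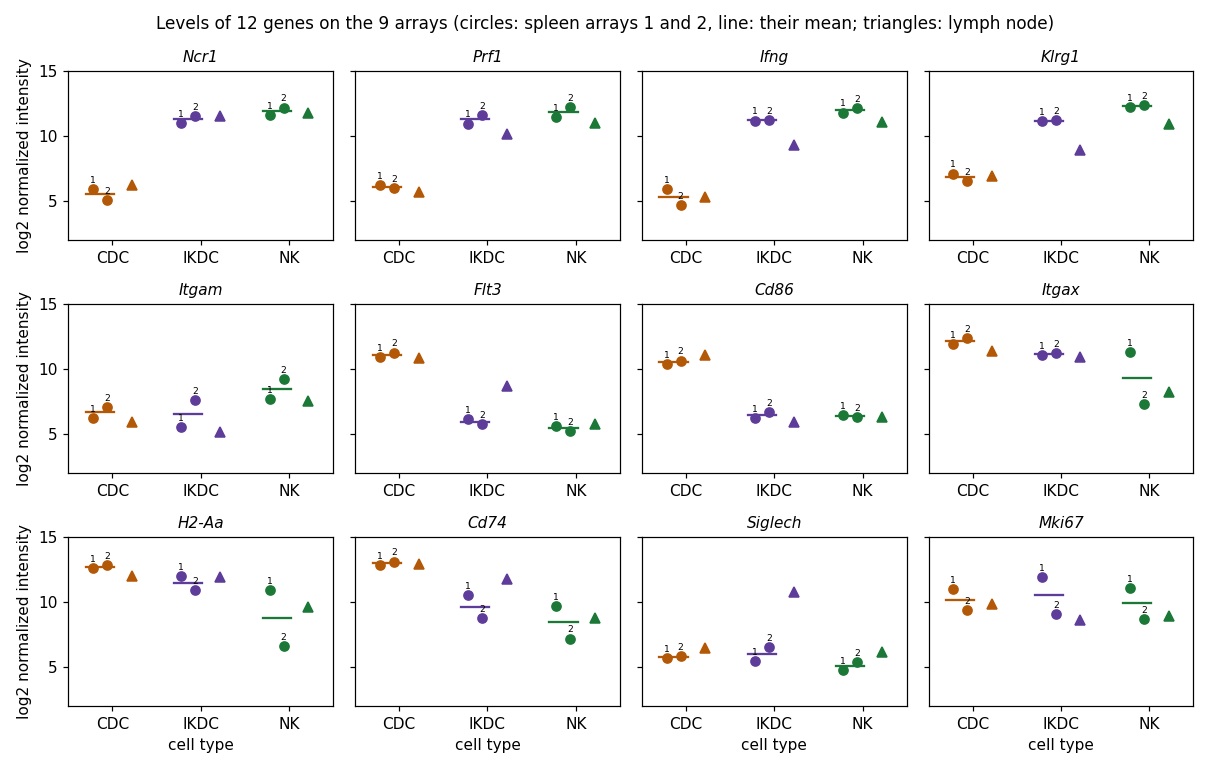
Log2 normalized intensity (vertical axis) of 12 genes in CDC, IKDC and NK; circles are spleen arrays 1 and 2 with a line at their mean, and triangles are the lone lymph node arrays. Ncr1, Prf1 and Ifng are high in IKDC and NK, and Itgax is at 11.32 on spleen NK array 1 and 7.27 on array 2.

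As groups, several gene sets differed between spleen IKDC and NK by camera, with no member called over all genes. Terminal NK maturation genes were lower in IKDC as a list (median -1.08, adjusted p = 5.09e-07, differences negative in 15 of 15 members), with a median of -0.92 between arrays 1, -0.868 between arrays 2 and -0.837 between the lymph node arrays. Adjusted over the list alone, 3 members were lower. The call was lost at adjusted p = 0.533 with an estimated correlation. NK receptor genes had a median of -0.397 (adjusted p = 0.00164) and cytotoxic effector genes -0.408 (adjusted p = 0.0296), each with adjusted p = 0.533 with an estimated correlation and 0 members called adjusted over the list alone. Klrk1 differed by -0.77 ± 0.23 and Gzmb by -1.08 ± 0.64.

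Class II presentation genes were higher in spleen IKDC than in NK (median 0.767, adjusted p = 2.03e-05, positive in 16 of 18, and 1 called adjusted over the list alone), and conventional DC genes too (median 0.708, adjusted p = 6.94e-06, positive in 26 of 33, and 0 called adjusted over the list alone). Both had adjusted p = 0.533 with an estimated correlation. The class II median was 0.378 between arrays 1, 1.2 between arrays 2 and 1.8 between the lymph node arrays, and the conventional DC median 0.554, 0.84 and 0.849. Spleen NK array 1 held high Itgax and H2-Aa but Flt3 at 5.6 and Cd86 at 6.5. Macrophage genes were higher in IKDC (median 0.518, 0.376 between arrays 1 and 0.768 between arrays 2, adjusted p = 0.00417, and adjusted p = 0.599 with an estimated correlation), while Lyz1, a lysozyme of myeloid cells chosen after its values were seen, read 6.70 and 11.37 on NK arrays 1 and 2 and 9.47 and 11.70 on IKDC arrays 1 and 2.

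Proliferation genes were higher in spleen IKDC than in NK (median 0.815, adjusted p = 0.00023, positive in 36 of 38, and adjusted p = 0.674 with an estimated correlation), with 0 members called adjusted over the list alone. The median was 0.983 between arrays 1, 0.528 between arrays 2 and -0.111 between the lymph node arrays, and these genes also split the spleen arrays by number. Type I interferon response genes had a median of 0.035 (adjusted p = 0.982). Mki67 differed by 0.60 ± 1.14. The block added plasmacytoid DC genes (median 0.255, 0.145 between arrays 1 and 0.331 between arrays 2, adjusted p = 0.0414) and early response genes (median -0.306, adjusted p = 0.0264) to the 7 lists called, both with adjusted p = 0.533 with an estimated correlation and no block. None of the camera calls in any comparison held with an estimated correlation, nor did those of the 3 spleen comparisons with the block. That setting has at most 3 residual degrees of freedom, so the loss does not show that correlation between genes made the calls. Early NK stage genes in IKDC against CDC had an estimated correlation of -0.0275, below the preset 0.01, and still lost their call. The 7 lists called between spleen IKDC and NK all had estimates above the preset. These were 0.935 for proliferation, 0.651 for macrophage, 0.502 for terminal NK maturation and 0.256 for class II genes. NK receptor, cytotoxic effector and conventional DC genes had 0.241, 0.159 and 0.0865. Where these estimates hold, camera at the preset gives adjusted p-values that are too small. All called lists had a median, mean and test of the same sign, and 6 of the 17 lists not called here had signs that differed.

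**Figure D3:**
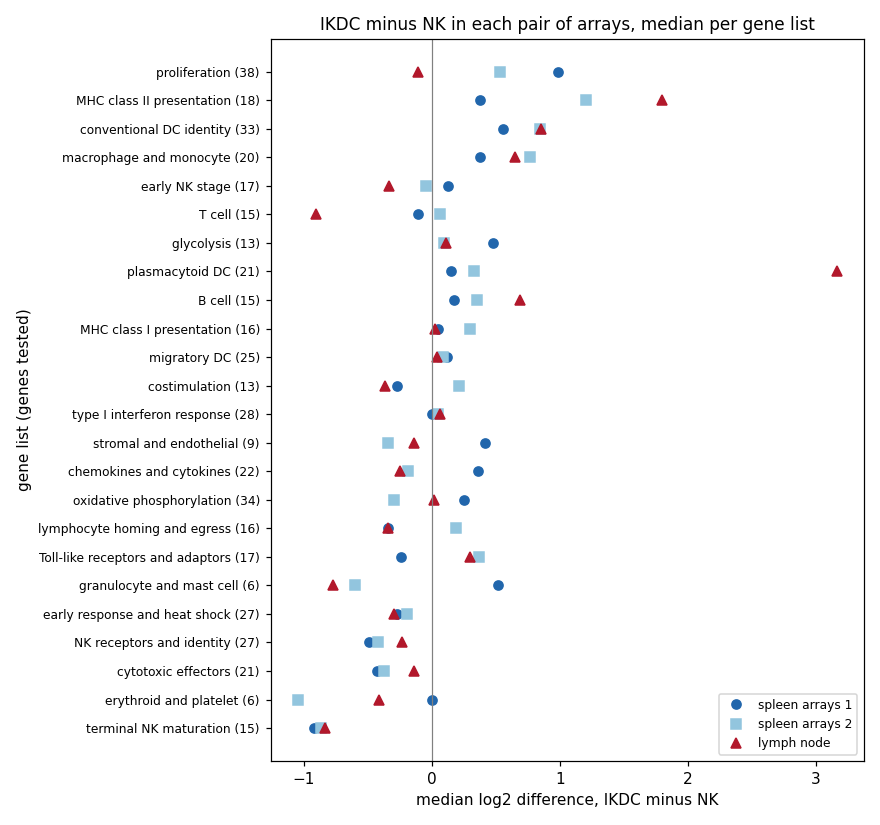
Median log2 difference of IKDC minus NK (horizontal axis) for each of 24 gene lists (vertical axis, genes tested in parentheses) in spleen arrays 1, spleen arrays 2 and the lymph node arrays. Terminal NK maturation lies at -0.92, -0.868 and -0.837, and plasmacytoid DC at 3.16 in the lymph node.

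IKDC shared most of their difference from CDC with NK. Genes such as Ncr1 and Prf1 were among the 457 called higher than CDC in both, and Flt3 and Havcr2 among the 550 called lower in both. Both comparisons use the same CDC arrays, so some overlap arises from sharing them, and simulated unchanged groups gave a correlation across genes of 0.498 where the data gave 0.914. With no shared arrays the correlation was 0.768 and 0.680. A scale from NK at 0 to CDC at 1 used the 1448 genes called between spleen NK and CDC with at least a 2-fold difference. The spleen NK and CDC arrays thus both chose these genes and set the ends of the spleen scale. The lymph node differences did not enter that choice. On this scale the lymph node IKDC array lay at 0.218 and the spleen IKDC arrays at 0.175 and 0.148. Over the 700 genes higher in NK these arrays lay at 0.112, 0.171 and 0.0738, and over the 748 higher in CDC at 0.301, 0.179 and 0.21. The lymph node IKDC array also held high plasmacytoid DC genes, a list median of 3.16 above lymph node NK, whose source stays open. Its position may thus not be that of IKDC alone.

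The lymph node differences did not enter the spleen calls, though these arrays counted in the filter and the choice of probe sets. They repeated the direction of the spleen differences in 1056 of 1129 genes (93.5%) for IKDC against CDC and in 1414 of 1473 (96.0%) for NK against CDC. Ncr1 was 40.2-fold higher in lymph node IKDC than in lymph node CDC, Prf1 22.6-fold and Ifng 15.4-fold. Between IKDC and NK no genes were called, so the 200 smallest p-values in each direction were taken, a choice made after the data were seen, and 281 of 400 (70.2%) kept their direction. Without spleen IKDC array 1 this share was 51.7%, and without spleen IKDC array 2 it was 89.8%.

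Lymph node IKDC were compared with spleen IKDC to find differences by organ. Plasmacytoid DC genes stood out. Siglech, a surface lectin of plasmacytoid dendritic cells, was at 10.78 in lymph node IKDC and at 5.45 and 6.51 in spleen IKDC. Ccr9, a chemokine receptor, was at 11.79 and Spib, a transcription factor of these cells, at 10.63, both chosen after their values were seen. The list was positive in 19 of 21 members, 13 called adjusted over the list alone (median 2.68, adjusted p = 9.02e-21, and adjusted p = 0.0702 with an estimated correlation). Conventional DC genes in lymph node IKDC lay a median of 0.849 above lymph node NK, positive in 23 of 33, with Flt3 2.92 and Itgax 2.70 above.

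Other groups also differed between lymph node and spleen IKDC. The 3' to 5' ratio of Gapdh, a sign of RNA quality, was 2.70 to 3.23 on the lymph node arrays and 3.28 to 6.15 on the spleen arrays, 3.23 and 3.28 being those of lymph node CDC and spleen CDC array 2. The actin ratio was 1.39 to 1.89 on the lymph node arrays and 1.11 to 3.23 on the spleen arrays. Early response genes, transcribed within minutes of a stimulus, were lower (median -1.35, adjusted p = 1.94e-15, 11 members adjusted over the list alone, and adjusted p = 0.0992 with an estimated correlation). Proliferation genes were lower (median -1.68, adjusted p = 4.43e-11, 0 members adjusted over the list alone, and adjusted p = 0.495 with an estimated correlation), by -2.87 against spleen array 1 and -0.737 against array 2. Class II genes were higher (median 0.92, adjusted p = 0.000103, 2 members adjusted over the list alone, and adjusted p = 0.373 with an estimated correlation), and B cell genes too (median 0.599, adjusted p = 0.00396, 2 members adjusted over the list alone, and adjusted p = 0.336 with an estimated correlation). Conventional DC genes were higher (median 0.489, adjusted p = 0.000269, 7 members adjusted over the list alone, and adjusted p = 0.336 with an estimated correlation), and cytotoxic effector genes lower (median -0.258, adjusted p = 0.00508, 0 members adjusted over the list alone, and adjusted p = 0.381 with an estimated correlation), by -0.166 against spleen array 1 and -0.489 against array 2. Limma called 0 single genes, with 744 at an unadjusted p under 0.05. With blocks chosen after the data were seen, it called 62 by Xist level and 199 by control spike ratio. The Xist block set the lymph node against the level of spleen arrays 2, and the spike block against that of spleen arrays 1. The spike difference stays inside the count with the Xist block, and the Xist difference inside that with the spike block. Fry called 2 of the 12 lists called by camera.

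Lymph node NK differed from spleen NK in early response genes, which were lower (median -1.08, adjusted p = 1.82e-10, 9 members adjusted over the list alone, and adjusted p = 0.135 with an estimated correlation), by -0.702 against spleen array 1 and -1.1 against array 2. T cell genes were higher (median 1.36, adjusted p = 4.83e-09, 5 members adjusted over the list alone, and adjusted p = 0.135 with an estimated correlation). Icos, a costimulatory receptor of T cells chosen after its values were seen, was at 11.19 in lymph node NK and at 7.78 and 8.41 in spleen NK. Early NK stage genes were higher (median 0.616, adjusted p = 5.68e-05, 3 members adjusted over the list alone, and adjusted p = 0.135 with an estimated correlation), among them Il7r, the interleukin 7 receptor, at 12.54 against 9.12 and 10.09, also chosen after its values were seen. Terminal NK maturation genes were lower (median -0.844, adjusted p = 0.000853, 2 members adjusted over the list alone, and adjusted p = 0.673 with an estimated correlation), by -0.183 against spleen array 1 and -1.29 against array 2. Proliferation genes were lower (median -0.741, adjusted p = 0.00147, 0 members adjusted over the list alone, and adjusted p = 0.822 with an estimated correlation), by -1.5 against spleen array 1 and -0.0734 against array 2. In all, 8 lists were called. Limma called 0 single genes, with 627 at an unadjusted p under 0.05, 3 with the Xist block and 14 with the spike block, and fry called 0 lists.

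Lymph node CDC were lower than spleen CDC in Nr4a1, an early response nuclear receptor, by 20-fold (-4.32 ± 0.28, adjusted p = 0.0271), in Pglyrp2 by at least 2.8-fold and in Ccl3, a chemokine, by 13.4-fold (both adjusted p = 0.049). Early response genes as a group were lower (median -1.75, adjusted p = 3.79e-16, 20 of 27 members adjusted over the list alone, and adjusted p = 0.181 with an estimated correlation). Migratory DC genes were higher (median 1.18, adjusted p = 1.04e-08, 6 members adjusted over the list alone, and adjusted p = 0.36 with an estimated correlation), by 1.36 against spleen array 1 and 0.823 against array 2, including Ccr7, the receptor that guides dendritic cells to lymph nodes, at 9.17 against 6.25 and 8.22, chosen after its values were seen. Limma called these 3 genes, 281 with the Xist block and 122 with the spike block. The count was 0 without spleen CDC array 1, CDC array 2, NK array 1 or NK array 2, 19 without IKDC array 1 and 16 without IKDC array 2. Of lists, 2 were called, 5 without CDC array 1 or with the Xist block, and 4 without CDC array 2 or with the spike block.

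Whether cell types differed in their change between organs was tested directly. The median standard error of these tests was 0.597, against 0.345 in the spleen comparisons, so a count of 0 is not evidence of a like change. By chance, 545 genes would have an unadjusted p under 0.05 in each test. Siglech, far higher in lymph node than in spleen IKDC, was not called in these tests. Limma called 0 genes for IKDC minus NK, 0 for IKDC minus CDC and 0 for NK minus CDC, with 302, 614 and 581 genes at an unadjusted p under 0.05 and smallest adjusted p of 0.455, 0.177 and 0.382.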

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

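The Xist, control spike and blocked estimated-correlation settings were chosen after the data were seen. Spleen IKDC versus spleen NK stayed at 0 genes and the organ differences and genes apart from both at 0 in every setting run. IKDC position between NK and CDC, for the lymph node IKDC array, was 0.205 to 0.226 with 1 array left out. The replicate block changed no other call than those given beside the results. The cause was not tested for any change below.

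Counts for spleen IKDC versus spleen CDC were 1872 with probe sets tested singly, where more features are tested, 1895 with additive cell type and organ, 2396 with Xist added and 1881 with the replicate block, and 359 to 1398 with 1 array left out. For spleen NK versus spleen CDC they were 2458, 2400, 2948 and 2310, and 510 to 1911. For lymph node CDC versus spleen CDC they were 5 with the same 75th percentile, 0 with no filter, 10 with the 60th percentile filter, 13 with log2 of value plus 1, 11 with the floor, 6 with the mean of probe sets, 0 singly, 0 with no trend, 1 with trend and robust, 281 with the Xist block, 122 with the control spike block and 0 to 19 with 1 array left out. For lymph node IKDC versus spleen IKDC they were 22 with the 60th percentile filter, 62 with the Xist block, 199 with the spike block and 0 to 12 with 1 array left out. For lymph node NK versus spleen NK they were 1 with no filter, 3 with the 60th percentile filter, 1 singly, 3 with the Xist block, 14 with the spike block and 0 with 1 array left out.

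With an estimated correlation, gene lists called were 0 in every comparison, and 0 in the 3 spleen comparisons with the replicate block as well. This setting has few degrees of freedom and could hardly call a list. Fry called 0 for spleen IKDC versus spleen NK, 11 for spleen IKDC versus spleen CDC, 14 for spleen NK versus spleen CDC, 2 for lymph node IKDC versus spleen IKDC, 0 for lymph node NK versus spleen NK and 1 for lymph node CDC versus spleen CDC, where the Xist block called 5 and the spike block 4. With 1 array left out the lists called were 6 to 10, 10 to 16 and 12 to 16 for spleen IKDC versus spleen NK, spleen IKDC versus spleen CDC and spleen NK versus spleen CDC, and 12 to 15, 8 to 12 and 2 to 5 for lymph node against spleen in IKDC, NK and CDC. The lymph node repeat was 92.3 to 97.2% for IKDC versus CDC, 95.3 to 98.2% for NK versus CDC and 51.7 to 89.8% for the 200 genes per direction of IKDC versus NK.

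Of the other values of named genes, 28 lost and 27 gained a call under settings that kept all arrays or the spleen arrays alone. Some also lost or gained one with 1 array left out. Signs reversed only in genes that were not called. With 1 array left out, in spleen IKDC versus spleen NK, Cd27 ranged from -0.391 to 0.999, Cd74 from -0.0435 to 2.46, Itgax from -0.187 to 3.86, Mki67 from -0.818 to 2.03 and Cd86 from -0.174 to 0.325. In spleen IKDC versus spleen CDC, Itgam ranged from -1.14 to 0.963, Mki67 from -1.09 to 1.75, Ptprc from -0.30 to 0.0153 and Siglech from -0.299 to 0.765. In spleen NK versus spleen CDC, Mki67 ranged from -1.45 to 0.901, Ptprc from -0.0927 to 0.222 and Tnfsf10 from -0.213 to 0.43. In both additive models Cd86 was -0.0715 in IKDC versus NK, and Mki67 was -0.189 and Ptprc 0.0873 in IKDC versus CDC. As deposited, Itgam was 0.00295 in IKDC versus CDC and Ptprc -0.0498 in NK versus CDC, where Ptprc was also -0.0208 with the same 75th percentile and -0.0157 with the mean of probe sets. Genes near the filter level of 5.31 lie close to the array background.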

Other observations

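All tests in this part were chosen after the results they address were seen.

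Mast cell and platelet genes had unlike values on the NK arrays, with no test. Cpa3, a mast cell protease, was at 6.01 on spleen NK array 1, 9.41 on array 2 and 7.44 on the lymph node NK array. Ms4a2, a chain of the IgE receptor, was at 5.44, 8.27 and 7.48, and Pf4, a platelet chemokine, at 5.95, 9.60 and 6.76. These genes were chosen after their values were seen.

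Itgax and class II genes were high on spleen NK array 1 and low on array 2. Conventional dendritic cells in that sort are argued against, since 23 conventional DC genes would need a median share of 1.75% CDC (quartiles -0.179 to 2.47%) where Itgax needs 65.8%. An IKDC sample under an NK label stays open: terminal NK maturation genes lay a median of -0.92 in IKDC array 1 relative to it, near the -0.868 of arrays 2 and -0.837 of the lymph node, which goes against it, but arrays 1 and 2 lay -0.648 apart in IKDC and -0.725 in NK, and the measure of spread was changed after these values were known. A share of IKDC in the sort stays open for the class II genes, since the gap in that list changed by a median of -0.144 (quartiles -0.372 to 0.141) from arrays 2 to arrays 1. Itgax lay 1.13 above its level at the highest share of cells like IKDC array 1 (52.3%). It lay 0.0952 above that for array 2, within the SD of 0.147 of the IKDC arrays, though at a share of 99.1%. The Xist of 11.43 on IKDC array 2 is far from the 6.36 of NK array 1, but Xist was not part of the test. The outcome depends on which IKDC array is the source, so a share of IKDC stays open for Itgax. Transcription by the NK themselves was not tested.

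Plasmacytoid DC genes were high in lymph node IKDC, with 90.5% of the 21 genes above lymph node NK. That share restates the pattern and gives no support to plasmacytoid dendritic cells in the sort, whose gates the labels used here do not state. Conventional dendritic cells are argued against, since the list lay a median of 1.83 above lymph node CDC (quartiles 0.866 to 3.70), where spleen replicates differed by a median size of 0.676 at most. Whether IKDC of the lymph node transcribe these genes themselves cannot be told apart from the presence of such cells, as NK receptor genes lay a median of -0.235 from lymph node NK (quartiles -0.684 to -0.0975) and no array of plasmacytoid dendritic cells alone was analysed here.

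Proliferation genes were higher on spleen arrays 1 than on arrays 2, by a median of 1.38 in CDC, 1.61 in NK and 2.02 in IKDC. The scaling of the arrays is argued against, since the lowest median under the other scalings was 1.42. A batch of the arrays marked by the control spikes could give the split. In 3 of 3 cell types, however, the lymph node array lay nearer spleen array 2 in this list. Its spike ratios lay nearer array 1, but the organ differs too, so such a batch stays open. Xist was 5.81 higher on spleen arrays 2, so the sex of the mice and the replicate number cannot be told apart.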
